A study of Mus musculus with 28 samples.

How the data were processed

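The series holds 28 chromatin immunoprecipitation sequencing (ChIP-seq) libraries of mouse cranial neural crest cells, the migratory embryonic cells that form most of the facial skeleton. The labels place them in 25 groups by embryonic day, cell population, genotype and antibody. Per the labels, cells of dissected embryos were fixed and, for the single-antibody libraries, collected by fluorescence-activated sorting. The antibodies were against acetylated lysine 27 of histone H3 (H3K27ac, a mark of active promoters and enhancers), H3K27me3 (the Polycomb mark) and H3K4me2. The labels list 5 H3K27ac, 8 H3K27me3, 8 H3K4me2 and 4 sequential H3K27me3 and H3K4me2 libraries, and 3 inputs. The measurements analysed here are 1 list of H3K27ac intervals, which rests on 4 libraries. The other 24 libraries were not analysed here.

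Per the text deposited with the list, reads of the 4 wild-type H3K27ac libraries of E10.5 (populations labelled FNP, Mx, Md and PA2, 1 library each) were merged and intervals were called on them together with MACS2 2.1.3.3, without model building, with a shift of 0, an extension size of 141 bp, duplicates kept and a q-value limit of 0.001. No control is named among those options. Per the submitters' processing notes, the tools include bcl2fastq 2.17 and Bowtie 1.1.1, and the builds are GRCm38 and mm10, 2 names of the same assembly. The list gives a chromosome, start, end and 1 score for each interval. The score is the authors' deposited value, which MACS2 by convention sets to the integer part of 10 times −log10 of the q-value, and it grows with the number of merged reads. The lowest score in the list, 31, lies just above the value that the stated q-value limit gives. Scores served to describe, rank and filter intervals within this list. Sequencing depth is unknown, and no interval carries a population, so populations could not be compared and no value has a replicate error. Duplicates kept and no named control mean that piled-up reads at repeated sequence can enter the list as intervals with very high scores.

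Gene positions came from a RefSeq gene table of GRCm38.p6, the same build as the list, with 21887 protein-coding genes on chromosomes 1 to 19, X and Y. The table used here has gene starts and ends but no strand, exons or sequence, which changed several tests from those fixed before the data were examined. A gene was scored as marked when an interval overlapped by at least 1 bp the 1 kb on either side of either annotated gene end, in place of its transcription start sites. Start sites inside a gene, as many regulators have, are missed, and an interval at the 3′ end counts. For Hox genes the 5′ end was taken from the shared direction of each cluster, with group 13 upstream of group 1. Score took the place of fold enrichment in every filter and ranking. Distal intervals, those away from every protein-coding gene end, were counted within 100 kb of each end of a gene and the 2 counts were averaged. Random placements kept each interval's chromosome and width, lay between the first and last interval of the chromosome, were not kept off assembly gaps and could overlap each other.

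Stitched regions joined distal intervals with gaps of at most 12 kb. They were to be ranked by fold enrichment times width. Without fold enrichment, they were ranked by covered length, one of the alternatives fixed beforehand, and this choice was made after the extreme scores in the list had been seen. Score times width, the nearest match to the original ranking, was run as an added alternative. The 500 highest-ranked regions were assigned to their nearest protein-coding gene.

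The share of intervals at gene ends was compared with 100 random placements, whose smallest 2-sided permutation p is 0.02. The 17 gene lists fixed before the data were examined, with 273 genes that all matched the table, were tested 3 ways. Shares with an interval at a gene end and shares nearest to a stitched region were compared with all other protein-coding genes by 2-sided Fisher's exact test. Median distal counts were compared with 10000 random lists of the same size, matched on the decile of the distance between neighbouring genes, by a 2-sided permutation test whose smallest p is 0.0002. All p-values of a family of 17 lists were adjusted by the Benjamini-Hochberg method, and adjusted values under 0.05 are called. Hox paralogue groups 1 to 3 were compared with groups 4 to 13 by 2-sided Fisher's exact test. Genes are not independent replicates, and neighbouring genes share intervals, so these p-values describe this list only and are too small where members are clustered. Some gene lists share members, such as Ednra in the neural crest and mesenchyme list and in the signalling list, so their tests are not independent.

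The list tests were tested on 20 simulated interval sets over the 21887 genes. A list with every member marked, a list with none marked and a list with 15 added distal intervals per gene were each called in 20 of 20 sets. Among 300 tests of the remaining lists, 4 were called at gene ends and 4 for distal intervals. The tests at gene ends included the list with added distal intervals, so not all of them were of unchanged lists. That list shares genes with the list whose members were all marked, and its added intervals could fall at gene ends. Genes in the simulated sets were otherwise marked independently of each other, and background intervals were placed at random. The clustering of real intervals was thus not simulated, and the planted effects were extreme. These counts do not show how the tests behave with clustered intervals or smaller effects.

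Named genes followed a rule fixed beforehand, with score in place of fold enrichment. Per list, up to 4 members with the highest score at a gene end and up to 4 without an interval could be named, and every member of the positional and Hox lists. The 10 gene ends with the highest scores, the nearest genes of the 15 highest-ranked stitched regions and the 5 distal intervals with the highest scores could be named as well. Other genes that are named were chosen after their values were seen. Tests of CpG content and of sequence motifs, and the alternatives that need a genome or strand, were not run. Alternatives used scores of at least 100, the higher-scored 50% of intervals, other windows, gaps, ranks and assignments. Intervals inside the gene, either Hox gene end, the lower-scored 50% of intervals, score times width, the tests of score and width per list and the gene families were added after seeing the data. Values of some list members are not reported here, although they count in their lists. The 246 intervals off chromosomes 1 to 19, X and Y entered no gene comparison. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.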

Results

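Acetylation of histone H3 at lysine 27 was mapped in sorted cranial neural crest cells of wild-type mouse embryos at E10.5, when the crest has reached the facial prominences and pharyngeal arches. The 4 populations, labelled FNP, Mx, Md and PA2, gave 1 library each, and intervals were called once on their merged reads. The list therefore shows where H3K27ac was found in the pool of the 4 populations. It has no replicates, its depth is unknown, and it cannot say in which population an interval was acetylated. Positions are given in GRCm38.

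The list held 125826 intervals that covered 48.6 Mb of the genome. Their median width was 271 bp (quartiles 185 and 471 bp, range 141 to 3351 bp), and 5233 of them had the smallest width of 141 bp, the extension size of the caller. The median score was 111, with quartiles of 75 and 253, and scores ran from 31 to 3194311. Scores of at least 100 were reached by 70561 intervals. On chromosomes 1 to 19, X and Y lay 125580 intervals. Autosomes carried between 44.8 and 67.8 intervals per Mb, the X chromosome 11.7 and the Y chromosome 0.789.

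The design asks first how acetylation was divided between promoters and distal sites. Of the intervals on chromosomes, 20724 (16.5%) lay within 1 kb of an end of a protein-coding gene. Random placements of the same intervals put 3.67% there (SD 0.0532 over 100 placements), so gene ends held 4.49 times the random share (permutation p = 0.02, the smallest that 100 placements can give). Another 40.8% lay inside genes, against 38.9% at random, and 42.7% lay between genes, against 57.4%. Intervals at gene ends were wider and had higher scores than others. Their median width was 602 bp (quartiles 334 and 915 bp) and their median score 1116 (quartiles 247 and 3321), while intervals between genes had medians of 247 bp and 100. The median width at gene ends was 2.45 times and the median score 11.3 times that of all other intervals. The share at gene ends depended on the score. It was 77.6% in the decile with the highest scores, 17.0 times the random share, and 3.65% in the decile with the lowest, 1.09 times the random share of 3.33% (SD 0.187).

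**Figure D1:**
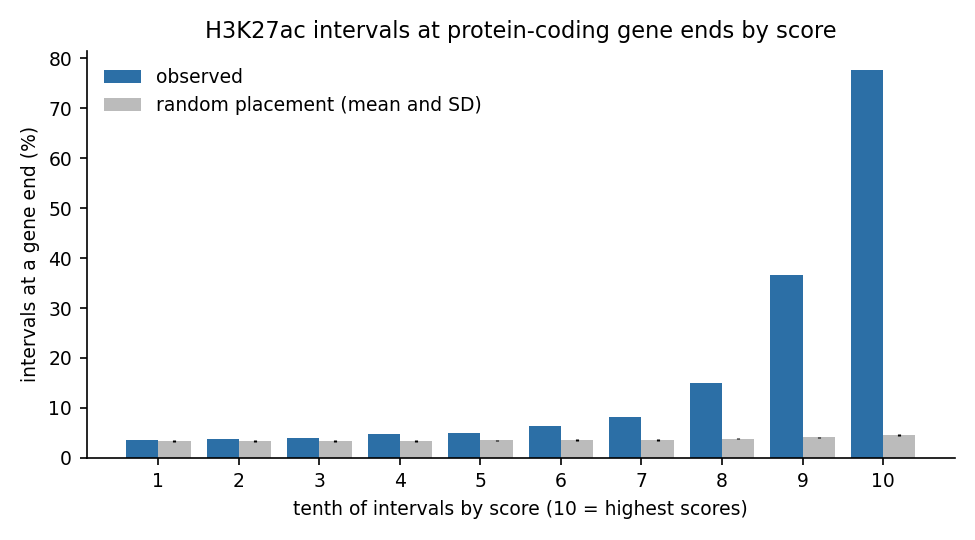
Percentage of H3K27ac intervals within 1 kb of a protein-coding gene end (y axis) in each decile of intervals by score (x axis, 10 = highest). Blue bars are observed shares and grey bars the mean of 100 random placements with their SD, and the observed share rises from 3.65% in decile 1 to 77.6% in decile 10.

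The highest scores at gene ends belonged to Cwc22, a splicing factor gene, with a score of 34699 (chromosome 2, 77945316 to 77946464), then Atp6v0c with 21652, Pcif1 with 21540, Sirt4 with 19512 and Gm40469 with 19171. Mdm2, which encodes the ubiquitin ligase of p53, had a score of 18825. Med16 and R3hdm4 shared an interval with a score of 18038, and Stam2 and Brpf1 had scores of 17885 and 17386. The Cwc22 interval was the only one at a gene end among the 25 with the highest scores in the list, of which 6 lay on scaffolds. With no control named for the caller, piled-up reads cannot be told from acetylation there. The highest scores therefore do not show which promoters were most acetylated. An interval lay at an end of 14235 of 21887 protein-coding genes (65.0%), and at both ends of 9.91%.

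All 8 frontonasal regulators, all 8 maxillary and oral-proximal arch regulators and all 11 mandibular and distal arch regulators had an interval at a gene end, against 65.0% of other genes. Among the frontonasal genes, Nr2f1, which encodes an orphan nuclear receptor, had a score of 2930, and the homeobox genes Alx4 and Alx1 had scores of 2683 and 1469. Pax7 had the lowest of that list at 339. Among the maxillary and oral-proximal genes, scores were highest at Dlx1 (1365), Barx1 (1243) and Lhx6 (855). Among the mandibular and distal genes, Gsc had a score of 1855, Dlx5 1407, Msx1 1380 and Msx2 1298, while Hand1 had 210. Fisher's exact test called only the mandibular list above other genes (exact test, adjusted p = 0.0368). With 8 members, the frontonasal and maxillary lists each reached an adjusted p of 0.0883 in the exact test, although no member was left unmarked. The mandibular call ended with a window of 2.5 kb (exact test, adjusted p = 0.0870) and with intervals anywhere in the gene (exact test, adjusted p = 0.145), where still all members had an interval and more of the other genes did. When an interval had to cover the gene-end base itself, the direction turned for all 3 lists, with 25% of the frontonasal, 25% of the maxillary and 18.2% of the mandibular genes against 32.6% of other genes (exact test, adjusted p = 1, 1 and 0.802).

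The general neural crest and mesenchyme regulators were marked in 25 of 26 members (exact test, adjusted p = 0.00164). Prrx2, a homeobox gene of facial mesenchyme, had a score of 4697, Tcf4 3530, Nfib 3469 and Twist1, a regulator of mesenchymal fate, 3067. The exception was Tfap2a, which lacked an interval at its annotated outer ends but had a stitched region over it. At the gene-end base itself the call ended and the share turned to 23.1%, below the 32.6% of other genes (exact test, adjusted p = 0.802). Craniofacial signalling genes were marked in 22 of 26 (exact test, adjusted p = 0.0797), with Notch2 at a score of 6902, Gli3 at 4860, Jag1 at 4648 and Tgfb3 at 4167. Bmp4, Ihh, Shh and Tgfb2 lacked an interval at a gene end. The signalling genes were called with a window of 2.5 kb (92.3%, exact test, adjusted p = 0.0444) and with intervals anywhere in the gene (96.2%, exact test, adjusted p = 0.0183). The latter setting was not matched on gene length, and longer genes can hold more intervals. Genes of premigratory and neural-glial crest were marked in 8 of 11 (exact test, adjusted p = 0.886). Erbb3, a glial receptor gene, had a score of 1442 there, whereas Zic1 was among those with no interval at a gene end. Cartilage and bone differentiation genes were marked in 10 of 14 (exact test, adjusted p = 0.886), including Sp7, an osteoblast regulator, at 3015 and the cartilage collagen gene Col2a1 at 2012, and not Bglap, Col9a1, Ibsp or Spp1.

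Genes for subunits of Polycomb and Trithorax complexes were marked in 25 of 30 (exact test, adjusted p = 0.0797), and were called with intervals anywhere in the gene (100%, exact test, adjusted p = 0.00177). That setting was not matched on gene length. Mtf2 had a score of 12125, Jarid2 9845, Rnf2 8807 and Rbbp4 8607, and Ash2l, Cbx7, Dpy30 and Kdm6b were among those without an interval at a gene end. Housekeeping genes were marked in 19 of 20 (exact test, adjusted p = 0.0155), with Rplp0 at 8445 and Ubb at 7670, and only Ywhaz lacked an interval at a gene end. Regulators of other lineages were marked in 4 of 20, below other genes (exact test, adjusted p = 0.000415). With intervals anywhere in the gene their share rose to 40%, still below the 74.4% of other genes (exact test, adjusted p = 0.005). Gata6 had a score of 481, Tbx5 134, Neurog1 110 and Wt1 75. Cdx2, Foxa2, Gata1 and Gata4, regulators of gut, endoderm, blood and heart, had no interval at a gene end. At the gene-end base itself the calls of both lists ended, with shares of 35% and 10% against 32.6% (exact test, adjusted p = 1 and 0.177).

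Markers of cells that a sorted fraction could contain gave mixed results. Blood markers were marked in 4 of 13, below other genes (exact test, adjusted p = 0.0458), and the call ended in all 5 alternatives (exact test, adjusted p = 0.0617 to 0.124). Spi1 had a score of 1492 and Klf1 1480, while the globin genes Hba-a1, Hba-x, Hbb-bt and Hbb-y had no interval at an end. Endothelial markers were marked in 12 of 13 (exact test, adjusted p = 0.0797), but with low scores, from 49 at Esam to 435 at Erg. Egfl7 had no interval at a gene end. They were called with a window of 2.5 kb (100%, exact test, adjusted p = 0.0444), but their share fell to 61.5% with scores of at least 100 (exact test, adjusted p = 1) and to 46.2% in the higher-scored 50% of intervals, below the 60.5% of other genes (exact test, adjusted p = 0.517). Epithelial markers were marked in 7 of 15 (exact test, adjusted p = 0.247), led by Grhl2 at 1367, with no interval at an end of Cdh1, Cldn6, Esrp1 or Grhl3. With intervals anywhere in the gene, their share was 73.3%, against 74.4% of other genes. Myogenic and mesoderm core markers were marked in 5 of 10 (exact test, adjusted p = 0.437), led by Myf6 at 380, and neuronal markers in 8 of 12 (exact test, adjusted p = 1), led by Elavl4 at 4646.

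**Figure D2:**
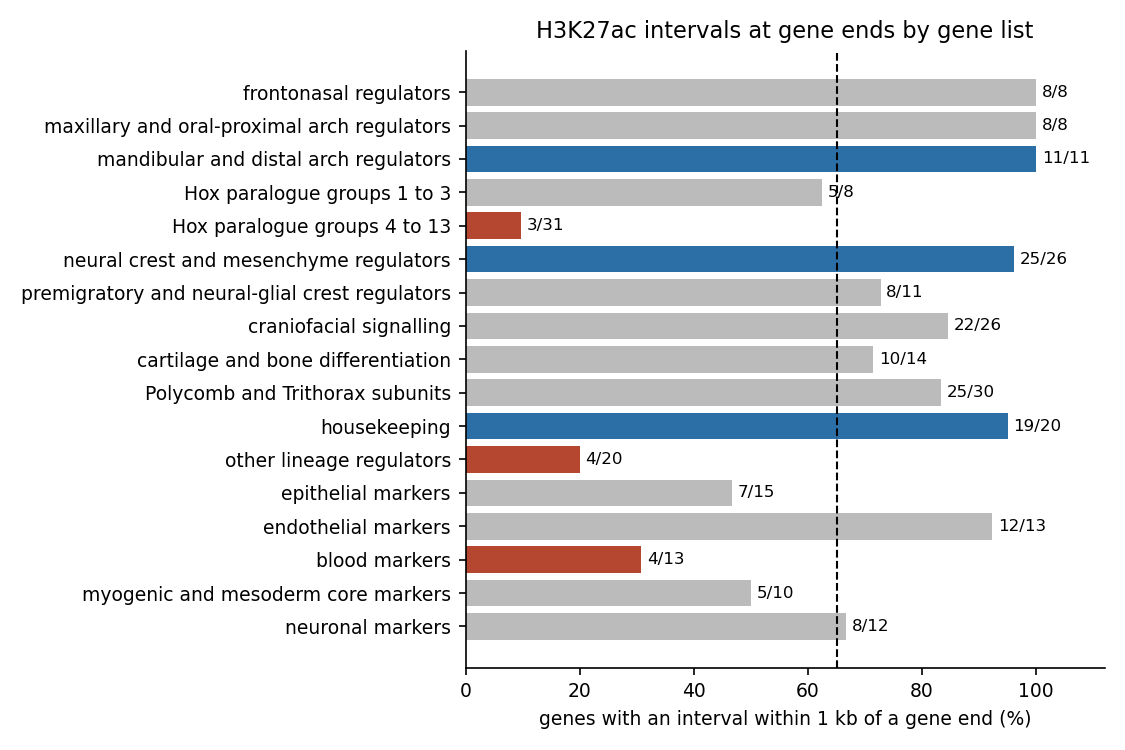
Percentage of genes with an H3K27ac interval within 1 kb of either gene end (x axis) in each of 17 gene lists (y axis), with marked and total members at each bar. Blue and red bars lie above and below other genes at an adjusted p under 0.05, grey bars do not, and the dashed line is the share of all protein-coding genes, 65.0%.

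Hox genes were largely without H3K27ac outside groups 1 to 3. Of the 31 genes of groups 4 to 13, 3 had an interval at an end, namely Hoxd13, Hoxd9 and Hoxd8, against 65.1% of other genes (Fisher's exact test, adjusted p = 3.59e-09). Of the 8 genes of groups 1 to 3, 5 had one (adjusted p = 1, exact test). Counting the inferred 5′ end, 4 of 8 genes of groups 1 to 3 (among them Hoxa2, Hoxb2 and Hoxd1) and 3 of 31 genes of groups 4 to 13 were marked (Fisher's exact test, p = 0.0222). The highest score was 800 at Hoxb2 (chromosome 11, 96352552 to 96353714), and Hoxa2, the Hox gene that sets second-arch identity, had 443 (chromosome 6, 52164140 to 52164608). Hoxd8 and Hoxd13 had scores of 211 and 204, Hoxd9 84 and Hoxd1 45. With scores of at least 100, the counts were 2 of 8 and 2 of 31, and the difference was no longer called (Fisher's exact test, p = 0.180). The annotated 5′ ends of Hoxa3, Hoxb3 and Hoxd3, all counted as unmarked, lay upstream of Hoxa4, Hoxb4 and Hoxd4. Any start site inside these long annotated genes was not tested. Because neighbouring Hox genes are not independent, the p-values are too small.

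The clusters differed in how many intervals they held. Hoxa held 10 intervals, with a run of them from Hoxa2 into the adjoining end of Hoxa3, from 52164140 to 52170531. Another had a score of 315 and lay between Hoxa7 and Hoxa9. Hoxb held 5, with 4 at or beside Hoxb2 and the other inside Hoxb3. Hoxd held 5 with a top score of 211. Hoxc, which has no gene of groups 1 to 3, held 0 intervals over 115.7 kb.

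**Figure D3:**
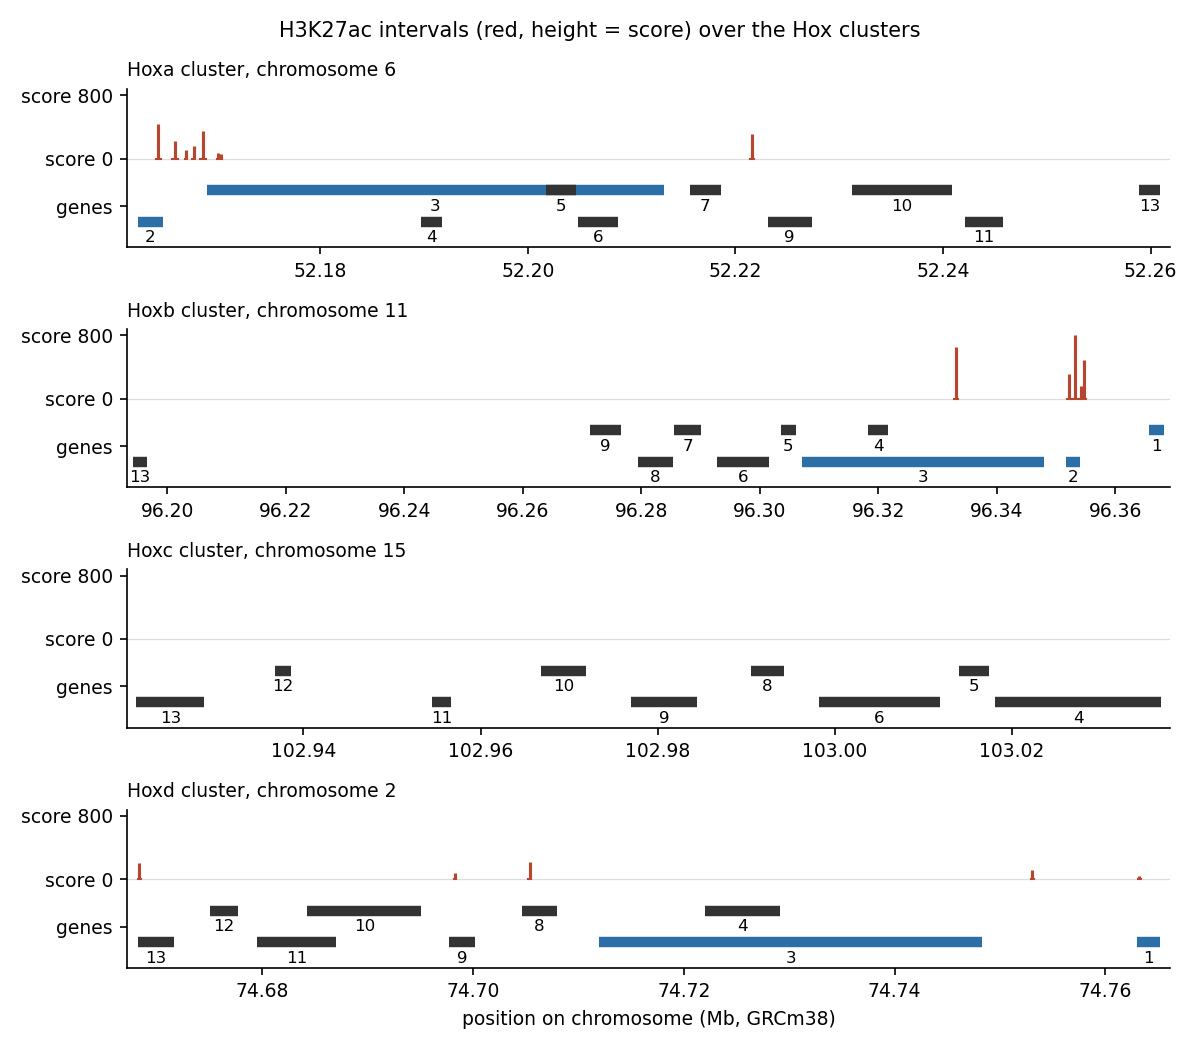
Maps of the 4 Hox clusters by position in Mb (x axis, GRCm38), with genes as bars numbered by paralogue group (blue for groups 1 to 3, black for others) and H3K27ac intervals as red lines whose height is the score (0 to 800). The Hoxa map starts at Hoxa2, intervals gather from Hoxa2 to Hoxa3 and at Hoxb2, and the Hoxc cluster has 0.

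Distal intervals were dense around the genes of face development. These intervals, also used for the stitched regions, can lie at start sites inside genes and at ends of non-coding genes. Ends of all annotated genes held 22.5% of intervals (7.45% at random), against 16.5% for protein-coding genes alone (3.67% at random). The median number of distal intervals within 100 kb was 18 for frontonasal regulators, against 7.25 in matched random lists (permutation test, adjusted p = 0.0141). It was 19.75 for maxillary regulators against 7.25 (permutation test, adjusted p = 0.00567) and 18.5 for mandibular regulators against 7.5 (permutation test, adjusted p = 0.00408). In the lower-scored 50% of intervals the frontonasal call ended (7.25 against 4.25, permutation test, adjusted p = 0.469). Neural crest and mesenchyme regulators had 19.75 against 7 and craniofacial signalling genes 17.5 against 7.25, both with an adjusted p of 0.0017, for which the unadjusted p was the smallest that the random lists can give. Cartilage and bone genes had 17.25 against 7.25 (permutation test, adjusted p = 0.00255). Single genes with many distal intervals were Alx4 with 41.5, Dlx2 with 37, Dlx1 with 36.5 and Prrx2 with 34, whereas Nkx3-2 had 2. Hox genes of groups 4 to 13 had 3 against 8 (permutation test, adjusted p = 0.00227), and those of groups 1 to 3 had 8.5 against 7.75 (permutation test, adjusted p = 0.920).

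The remaining lists were not called in the main setting. Endothelial markers had 13.5 against 7.5 (permutation test, adjusted p = 0.0582), epithelial markers 11 against 7.5 (0.284), housekeeping genes 10 against 7.5 (0.295), Polycomb and Trithorax genes 9 against 7.25 (0.483) and blood markers 8 against 7 (0.920). Premigratory and neural-glial crest genes had 7 against 7 and myogenic markers 7 against 7.25 (permutation test, both adjusted p = 1). Neuronal markers had 6 against 7.5 (0.851) and regulators of other lineages 4 against 7.75 (0.152). Housekeeping genes were called above random lists with scores of at least 100 (8 against 4, permutation test, adjusted p = 0.00544), in the higher-scored 50% of intervals (7.5 against 3.5, permutation test, adjusted p = 0.0034) and within 50 kb (6.5 against 3.25, permutation test, adjusted p = 0.00765). When each distal interval was assigned only to its nearest gene end, 2 of the 7 calls were left. They were those of the neural crest and mesenchyme list and of the signalling list, which share genes. The medians of the lists that lost the call were still above random there, at 26 against 8.5 for frontonasal, 18.5 against 5 for maxillary, 10 against 4 for mandibular and 9 against 3 for cartilage and bone genes, while Hox groups 4 to 13 had 0 against 0. The Hox call also ended in the lower-scored 50% of intervals (2 against 3.5, permutation test, adjusted p = 0.21) and when 1 gene was kept per run of members closer than 200 kb to each other, which left 4 genes with a median of 3.5 against 8 (permutation test, adjusted p = 0.291).

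**Figure D4:**
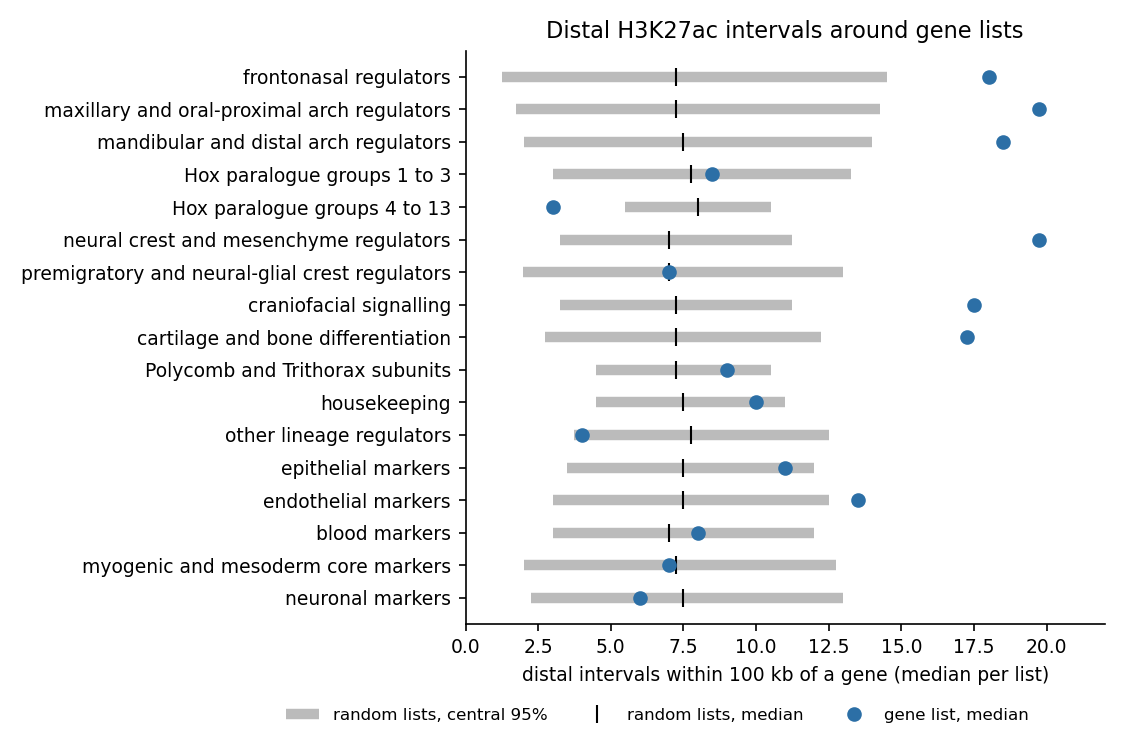
Median number of distal H3K27ac intervals within 100 kb of a gene (x axis) for each of 17 gene lists (y axis). Blue points are the lists, black ticks the median and grey bars the central 95% of 10000 matched random lists, and the frontonasal, maxillary, mandibular, neural crest, signalling and cartilage lists lie to the right of their bars, as do endothelial markers, which were not called after adjustment, while Hox groups 4 to 13 lie to the left.

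Distal intervals were also stitched into 41217 regions, of which 18965 held 1 interval. The 500 regions with the longest covered length, from 4.81 to 33.5 kb, were nearest to 454 protein-coding genes. Neural crest and mesenchyme regulators were nearest to such a region in 9 of 26 members, against 2.04% of other genes (Fisher's exact test, adjusted p = 2.55e-08), among them Nfia, Prrx2, Ednra and Snai1. Craniofacial signalling genes were in 6 of 26 (exact test, adjusted p = 0.000106), among them Smad7, an inhibitor of TGF-beta signalling, whose region on chromosome 18 (75370312 to 75538356) held 38 intervals. Ednra is in the signalling list as well and counts in both calls, which are thus not independent. Frontonasal regulators were in 3 of 8 (Alx4, Nr2f2 and Nr2f1; exact test, adjusted p = 0.0026) and maxillary regulators in 2 of 8 (Pou3f3 and Barx1; exact test, adjusted p = 0.047). Mandibular regulators had 1 of 11 (Hand2), cartilage and bone genes 1 of 14, myogenic markers 1 of 10 and blood markers 1 of 13 (exact test, each adjusted p = 0.541 in the exact test), and the other 9 lists had 0. Unlike the distal counts, this test was not matched on the distance between neighbouring genes. With each distal interval assigned to its nearest gene end, random lists matched to frontonasal regulators had a median of 8.5. Those matched to housekeeping genes had 0. Gene spacing can therefore enter the stitched calls and was not separated from them. The calls also depend on the settings. Cartilage and bone genes were called at 21.4% with scores of at least 100, in the higher-scored 50% of intervals and with a stitching gap of 5 kb (exact test, adjusted p = 0.0158, 0.0159 and 0.0102), and mandibular regulators at 27.3% with promoter intervals kept (exact test, adjusted p = 0.00649). The maxillary call ended with a gap of 5 kb (12.5% of members, exact test, adjusted p = 0.42) and among the top 250 regions (0%, exact test, adjusted p = 1). Ranking by score times width, the nearest match to the ranking planned before the data were examined, ended all 4 calls, each with an adjusted p of 1, and called only the Polycomb and Trithorax list (20% of members, exact test, adjusted p = 0.000781).

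The region with the longest covered length lay over 4930558K02Rik and Dnm3 on chromosome 1 (161975935 to 162220966), with 74 intervals and 33.5 kb covered. The next lay over Cstad on chromosome 2 (30600553 to 30801833), with 48 intervals, and the third 28.5 kb from Foxl1, a forkhead gene, with 57. The others of the first 15 were nearest to Hrh1, Hdac9, Gm40514, Rufy4, Smad7, Dapk1, 1700122O11Rik, Haao, Rbfox2, Alkbh8, Tspan9 and Col23a1. The region nearest to Alkbh8, on chromosome 9 from 3000008 to 3038281, lay 297 kb from that gene and had a median score of 7533, while the other 14 had median scores from 96 to 515.5. The distal intervals with the highest scores were on chromosome 2 at 98666267 to 98667384 (score 3194311) and 98662154 to 98662979 (447764), chromosome 12 at 3109786 to 3110151 (903469), chromosome 9 at 35305152 to 35305679 (713528) and chromosome 6 at 103648970 to 103649378 (526687). Their distances to the nearest protein-coding gene ran from 29.2 to 1035 kb. All 5, and 2 intervals of the region nearest to Alkbh8, were among the 25 with the highest scores in the list, of which 6 lay on scaffolds. With no control named for the caller, these scores cannot be taken as acetylation.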

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

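The tests of the highest scores were chosen after the result was seen. Intervals appeared in sequence that the gene comparisons did not use. On scaffolds and the mitochondrial genome lay 246 intervals, 3 of them mitochondrial, and no control sample was analysed beside them. Their median score was 473.5, against 111 on the chromosomes, and their highest was 426080.

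The 25 intervals with the highest scores in the whole list had scores of at least 34584. Of the 19 on chromosomes, 5.26% lay at a protein-coding gene end. The share was 77.8% in the rest of the decile with the highest scores there (Fisher's exact test, p = 2.79e-11). This argues against strong acetylation at gene ends as the source of these 25 scores only. It restates the place of the Cwc22 interval given above, and does not show where acetylation was strongest in the rest of the list. Reads piled up on repeated or collapsed sequence may account for the 25, because 24% of them lay on scaffolds, against 0.196% of all intervals. Some of the 25 lie beside each other, as on chromosome 14 between 19415642 and 19418988. They are not independent, so the p-value is too small. The inputs were not analysed here, so copy number and repeats could not be measured directly. No biological explanation other than acetylation at gene ends was tested.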

How the results depend on the processing

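No paired analysis was possible because the list was called on merged reads and carries no value per sample. The share of intervals at gene ends lay above random in every alternative run, with values from 5.32% at the gene-end base itself to 28.7% in the higher-scored 50% of intervals. The random share changed with the setting and was 0.645% and 3.94% in these. Relative to random, the share was lowest with a window of 2.5 kb (2.64 times) and highest at the gene-end base itself (8.24 times). Filtering left 70561 intervals with scores of at least 100 and 63171 in the higher-scored 50%, by construction. The median width at gene ends was 1.82 and 1.71 times, and the median score 8.79 and 8.13 times, that of other intervals in these subsets. No intervals overlapped or touched, so merging changed nothing. The alternatives that need strand or a genome, and those of the CpG and motif tests, were not run. Depth is unknown, so weak intervals cannot be told from missing ones. Alternatives added after seeing the data were intervals anywhere in the gene, either Hox gene end, the lower-scored 50% of intervals and score times width. Unless stated, the cause was not tested. Over all results, 237 values under alternatives were labelled the same. For single lists and the Hox difference, this means that they neither turned in direction nor crossed the threshold. Counts of called lists were judged by the size of the change alone. Without a turn, 24 values lost their call and 11 gained one. Another 11, judged by the size of the change, moved. A further 47 turned, mostly of lists that were called under neither setting.

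With the gene-end base itself, 1 of 6 list calls was left, Hox groups 4 to 13. Shares turned below the other genes for mandibular (18.2%) and neural crest genes (23.1%), whose calls ended, and for frontonasal (25%), maxillary (25%), premigratory crest (18.2%), cartilage (28.6%), endothelial (23.1%) and neuronal genes (8.33%), which had no call. Calls ended for housekeeping (35%), other lineages (10%) and blood (0%), and the Hox difference was 0 points. With 2.5 kb, the mandibular call ended at 100% and the blood call at 46.2%, signalling (92.3%) and endothelial markers (100%) were called, and neuronal markers turned below other genes at 66.7%. With intervals anywhere in the gene, mandibular (100%) and blood (46.2%) calls ended, signalling (96.2%) and Polycomb genes (100%) were called, and Hox groups 1 to 3 turned above other genes at 75%. With scores of at least 100 and in the higher-scored 50%, blood markers stayed at 30.8% but lost the call, the Hox difference fell from 40.3 to 18.5 points, and premigratory crest (54.5%) and neuronal genes (58.3%) turned below other genes. In the higher-scored 50%, endothelial markers turned below at 46.2%.

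With the nearest gene end, 2 of 7 distal calls were left. Medians were 26 for frontonasal, 18.5 for maxillary, 10 for mandibular, 9 for cartilage and 0 for Hox groups 4 to 13. Those Hox genes lost the call at 3.5 with 1 gene per run, where fewer genes were tested, and at 2 in the lower-scored 50%, where frontonasal genes at 7.25 lost it too. Among lists with no call in the main setting, housekeeping genes were called at 8 with scores of at least 100, 7.5 in the higher-scored 50% and 6.5 within 50 kb, and turned below random at 3 in the lower-scored 50%. Hox groups 1 to 3 turned below random at 3.5 with scores of at least 100, 2.5 in the higher-scored 50%, 3 within 50 kb and 7 with 1 gene per run. Myogenic markers turned above at 4.5, 4 and 4.5 in the first 3 of those settings and at 5.5 with the nearest gene end.

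Score times width left none of the 4 stitched calls, with shares of 12.5% for frontonasal, 0% for maxillary and 3.85% for neural crest and signalling genes, and its 1 call was the Polycomb list at 20%, which turned from below to above other genes. Under that ranking, mandibular, cartilage, blood and myogenic genes turned below at 0%, and housekeeping (5%) and epithelial genes (6.67%) above. The maxillary call also ended at 12.5% with a gap of 5 kb and at 0% with the top 250 regions, where fewer regions were tested and mandibular, blood and myogenic genes also turned below at 0%. With scores of at least 100, in the higher-scored 50% and with a gap of 5 kb, Polycomb genes (6.67%) and housekeeping genes (5%) turned above, and cartilage genes were called at 21.4%. Endothelial markers turned above at 7.69% and myogenic markers below at 0% with a gap of 5 kb, and blood markers below at 0% in the higher-scored 50%. With promoter intervals kept, mandibular genes were called at 27.3%, Polycomb genes turned above at 3.33% and blood markers below at 0%.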

Other observations

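The gene families, the scores and widths per list, and the tests of dilution and of width were chosen after the data were seen. Families were matched by symbol alone. Some had few intervals at gene ends. Of 1110 olfactory receptor genes, 8 (0.721%) had one, as had 3 of 353 vomeronasal receptor genes (exact test, adjusted p = 1.52e-155), 6 of 56 keratin-associated protein genes (exact test, adjusted p = 1.93e-16) and 4 of 42 beta-defensin genes (exact test, adjusted p = 2.91e-13). Cytochrome P450 genes had 23 of 90 (exact test, adjusted p = 1.58e-13). Nearly all genes had an interval in other families, with 79 of 83 for symbols of cytosolic ribosomal proteins (exact test, adjusted p = 1.87e-10), 40 of 40 for complex I (exact test, adjusted p = 9.09e-08) and 39 of 40 for the proteasome (exact test, adjusted p = 2.04e-06). These matches also hold genes of restricted use, and Psmc3ip, which is not a proteasome subunit and is named here after its value was seen. Developmental families lay between and none was called by Fisher's exact test over 16 families. Collagens had 35 of 44 (exact test, adjusted p = 0.0998), forkhead genes 34 of 44 and Fgf genes 18 of 22 (both 0.159), Sox genes 15 of 20 (0.552), T-box genes 12 of 17 (0.801), Wnt ligands 11 of 19 (0.673), LIM homeobox genes 6 of 12 (0.448) and Pax genes 3 of 9 (exact test, 0.119).

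Marked genes differed in the score and width of their best interval, compared with random lists of marked genes (permutation tests, adjusted over 17 lists). Housekeeping genes had a median score of 5988 (permutation test, adjusted p = 0.0085) and Polycomb and Trithorax genes 5304 (permutation test, adjusted p = 0.00907), against 2503 and 2522 in random lists. Neural crest and mesenchyme regulators had intervals of a median 1212 bp (permutation test, adjusted p = 0.0017), signalling genes 1390 bp (permutation test, adjusted p = 0.0017) and frontonasal regulators 1363.5 bp (permutation test, adjusted p = 0.01105), against 808.5 to 812 bp in random lists, while their scores of 1219, 1834.5 and 1345.5 were not called. Widths lay below random at Hox groups 4 to 13 (244 bp, permutation test, adjusted p = 0.0491), other lineages (252 bp, permutation test, adjusted p = 0.0143), endothelial markers (327.5 bp, permutation test, adjusted p = 0.0034) and neuronal markers (415 bp, permutation test, adjusted p = 0.0317). Lists below random in score were cartilage and bone (311) and other lineages (122) (both adjusted p = 0.0187 by permutation), neuronal markers (206.5, permutation test, adjusted p = 0.0187), epithelial markers (223, adjusted p = 0.0364), premigratory crest genes (349.5) and myogenic markers (156) (both adjusted p = 0.0385 by permutation). Endothelial markers had the lowest median of the 17, 112.5 (permutation test, adjusted p = 0.0034).

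Median scores at the frontonasal, maxillary, mandibular and mesenchyme regulators lay below those of random lists, but none of these differences was called (permutation tests, adjusted p = 0.344, 0.136, 0.0932 and 0.102). A hypothesis for lower scores, if they hold, is dilution in the merged reads of marks carried by only some populations. It needs lower scores at the 27 positional regulators than at the 25 mesenchyme regulators, taken here as shared by the populations. The medians were 1038 and 1219, and a permutation test of the difference gave p = 0.565, so dilution remains open, because the list cannot be split by population. Narrower marks at either group are argued against, because median widths of 1021 bp at the positional and 1212 bp at the mesenchyme regulators lay above those of random lists of marked genes, 808 and 812 bp (permutation tests, adjusted p = 0.0326 and 0.0008). The maxillary and mandibular lists alone were not called in width.

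Low-scored intervals at 12 of 13 endothelial markers may reflect endothelial cells in the sorted fractions or weak acetylation of these genes in the crest itself. Background intervals that fall at any gene are another possibility. The endothelial share lay above the 0.721% of olfactory receptor genes (Fisher's exact test, p = 2.05e-22). Closed receptor clusters may, however, be a lower background than other silent genes. Even Hox groups 4 to 13 lay above that share, at 9.68%, and blood and other-lineage genes had 4 of 13 and 4 of 20. The comparison therefore cannot exclude background intervals. The endothelial median score, 112.5, was near the median of all intervals, 111. In another list of 24 endothelial genes, written before its values were seen, 19 had an interval, with a median score of 300 (Fisher's exact test against other genes, p = 0.198), which leaves other cells open. Clec14a (1545) and Fli1 (1372) had the highest scores there and Tal1 is also in the blood list. Cells were collected by fluorescence-activated sorting, per the labels, and the share of other cells is unknown.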
